A study of Rattus norvegicus with 3 samples.

How the data were processed

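Gene expression was measured in cultured neonatal rat ventricular myocytes with 3 Affymetrix rat arrays, 1 for unstimulated cells, 1 for cells cultured with 20 µM phenylephrine and 1 for cells cultured with 1 µM PAMH. Per the labels, each culture lasted 48 h and total RNA was measured. The deposited values are signal intensities on a linear scale, 1 per probe set and array, for 15923 probe sets. The software and settings behind the deposited intensities are not given in the sources used here. The mean intensity after trimming 2% of the probe sets at each end was 250.1 on each of the 3 arrays, the result that scaling each array to a common trimmed mean gives, although the sources used here record no such step. Detection calls and saturation marks were not used here.

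The arrays had 57 control probe sets and 15866 others. In the platform annotation, 12783 of these carried 1 gene symbol, 312 carried several and 2771 carried none. Symbols were updated through the gene identifier in a current rat gene table, in which 12754 of the probe sets with 1 symbol were found, and they stood for 10411 genes. Probe sets with several symbols or none were left out of the gene comparisons. No coordinates were used, because the annotation names no genome build.

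Each array was multiplied by 1 factor so that the medians over non-control probe sets were equal. The factors were 0.937 for the unstimulated array, 1.02 for the phenylephrine array and 1.04 for the PAMH array. On the deposited values the median of all non-control probe sets differed from that of the unstimulated array by a log2 ratio of -0.13 on the phenylephrine array and -0.15 on the PAMH array. All ratios below are relative to this shift. They are not centred on the measured genes, whose median log2 ratios after scaling were 0.07 with phenylephrine and 0.10 with PAMH. A floor was set at percentile 40 of the scaled values of all arrays, which was an intensity of 76.0. The share of probe sets above it was 60.0% on the unstimulated array, 60.1% on the phenylephrine array and 60.0% on the PAMH array. A gene with several probe sets was represented by the brightest, by mean signal over the 3 arrays. A ratio was computed only where both arrays lay at or above the floor. Where 1 array was below the floor and the other above percentile 75, the brighter signal over the floor was given as a lower bound on the fold.

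With 1 array per group there were no replicates. The design therefore gave no standard errors or p-values, and the number of arrays limits the precision of every ratio. Genes were counted at a threshold of 2-fold. As a technical yardstick, the spread of the log2 ratio between probe sets of the same gene was computed. Its SD was 0.26 over 864 genes for phenylephrine against unstimulated, 0.28 over 867 genes for PAMH against unstimulated and 0.23 over 866 genes for PAMH against phenylephrine. This spread holds no variation between cultures.

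The gene comparisons, 34 gene lists, the rule for naming genes and all processing alternatives except those named as added were fixed before the data were examined. The lists for oxidative phosphorylation, cytosolic ribosomal proteins, translation factors, the proteasome and tRNA synthetases were drawn by patterns in gene symbols. They may therefore hold genes that only share such a symbol. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 classes. The matching was needed because the ratio depended on signal: against the unstimulated array, the brightest class of genes had a median log2 ratio of 0.24 with phenylephrine and 0.31 with PAMH, and the dimmest 0.00 and 0.01. A list was said to stand apart where its median lay outside the central 95% of the random lists. The resulting percentile describes these 3 arrays and is not a test of the treatments. Within a list, members were counted as higher or lower at 1.5-fold. The text names the 10 genes with the highest and the 10 with the lowest ratio in each comparison among genes with a mean signal above percentile 60, up to 4 genes per direction known only by a bound, the 4 members furthest in the direction of each list that stood apart, and a fixed panel of genes for hypertrophy and for α1-adrenergic and serotonin receptors.

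Both compounds were compared with the same unstimulated array, so their ratios share that array's deviations. The correlation of the ratios was set beside 1000 simulated sets of 3 unchanged arrays with normal deviations of the size seen in each signal class. The share of genes with the same sign with both compounds was set beside the same simulations, a step added after seeing the data. Counts of genes shared by both comparisons were also set beside the number that independent lists of the same lengths would share.

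The computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for quantile and cyclic loess normalization. It was tested on simulated arrays for the comparison of phenylephrine with unstimulated cells, with 6497 genes. Their base levels were the geometric means of the 3 arrays. Their noise came from the difference between the 2 treated arrays, the pair with the smallest SD of log2 ratios (0.289, against 0.432 and 0.411 for phenylephrine and PAMH over unstimulated). All measured genes simulated at 3-fold higher (25) or 3-fold lower (19) passed 2-fold, as did 40.0% of those simulated at exactly 2-fold higher and 33.3% of those at exactly 2-fold lower. Of the unchanged genes, 0.127% passed, a share that holds for this noise only. With deviations taken from all 3 arrays, which include real differences, 37.1 of 6399 unchanged genes were at least 2-fold higher per comparison on average. Of 25 genes simulated at 4-fold lower, 14 stayed above the floor and were measured, and 92.9% of these passed 2-fold, so these shares leave out genes that dropped below it; a first version that counted them did not pass, and the shares were then taken over measured genes. A first run with 100 unchanged lists of 20 genes had 12 apart where 5 would be by chance, after which the number of lists was raised; of 400 lists, these 100 included, 23 stood apart. Of 20 lists shifted by a log2 ratio of 0.3, 19 were found.

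The alternatives were the deposited intensities without a factor, quantile normalization, scaling on percentile 75, cyclic loess, floors at percentiles 20 and 60, no filter, the mean of all probe sets of a gene, genes with 1 probe set, an offset of 50 before taking logs, thresholds of 1.5-fold and 3-fold, and random lists without matching on signal. Scaling on 9 hybridization spike controls, and simulated deviations taken from the pair of treated arrays, were added after seeing the data.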

Results

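Messenger RNA levels were compared between ventricular myocytes from newborn rats kept in culture for 48 h without stimulus, with 20 µM phenylephrine or with 1 µM PAMH. Phenylephrine is an agonist of α1-adrenergic receptors that is widely used to make cultured cardiac myocytes grow. PAMH is the name the submitters give to the other compound, and their keywords include hypertrophy, 5-hydroxytryptamine and pyridine. The doses of the 2 compounds differed, so their responses are set side by side and not at matched dose. Each condition had 1 array and there were no replicates, so no difference below has a replicate check. The deposited median intensity was 118 on the unstimulated array, 108 on the phenylephrine array and 106 on the PAMH array. The ratio of the 3′ to the 5′ control probe set, a sign of RNA integrity, was 1.72, 1.44 and 1.54 for actin and 1.04, 1.07 and 1.01 for Gapdh, in the same order of arrays.

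The first comparison asked which genes differed between phenylephrine-treated and unstimulated myocytes. Genes of the fetal and stress-responsive cardiac program were higher on the phenylephrine array, with a median of 2.37-fold over 15 genes, 13 of them at least 1.5-fold higher and none lower. Nppb, which encodes B-type natriuretic peptide, was 3.99-fold higher, Nppa, which encodes atrial natriuretic peptide, 2.26-fold, and Acta1, the skeletal α-actin of fetal heart, 2.14-fold. Rcan1, a regulator and target of calcineurin, was 2.73-fold higher. Sarcomere and Z-disc genes and cholesterol synthesis genes were also higher, while genes of the oxidative stress response were lower relative to genes of like signal. Of 6570 genes measured on both arrays, 172 were at least 2-fold higher and 50 at least 2-fold lower with phenylephrine.

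The fetal and stress-responsive list had a median log2 ratio of 1.24, against 0.21 for the median random list, and lay at percentile 100. Other members were Myl4, the atrial and fetal myosin light chain (6.20-fold higher), Fhl1, a LIM-domain protein of the sarcomere (3.19-fold), and Gdf15, a stress-induced cytokine (3.27-fold). Of the paired myosin heavy chains, the β chain Myh7 was higher by a log2 ratio of 0.59, which became 0.20 after cyclic loess normalization, and its second probe set gave 1.13. The α chain Myh6 had a log2 ratio of -0.03 and a second probe set at -0.60. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a ratio of -0.05, with further probe sets at -0.22 and -0.16. After cyclic loess Myh6 and Atp2a2 had -0.41 and -0.39. The 9 measured genes of adult myocyte function lay within random lists at percentile 4.27, but below them under 4 of 10 alternatives, among these quantile normalization (percentile 0.585) and cyclic loess (0.090). After cyclic loess the log2 ratios of Nppa and Acta1 were 0.78 and 0.74, below 2-fold. Of the 24 sarcomere and Z-disc genes, 13 were at least 1.5-fold higher and none lower, with a median log2 ratio of 0.60 at percentile 100. Tcap, which encodes the titin cap protein, was 3.93-fold higher, Pdlim3 of the Z-disc 3.14-fold and Csrp3, the muscle LIM protein, 3.04-fold. Acta1, Myh7, Myl4, Tnni1 and Csrp3 belonged to both of these lists.

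**Figure D1:**
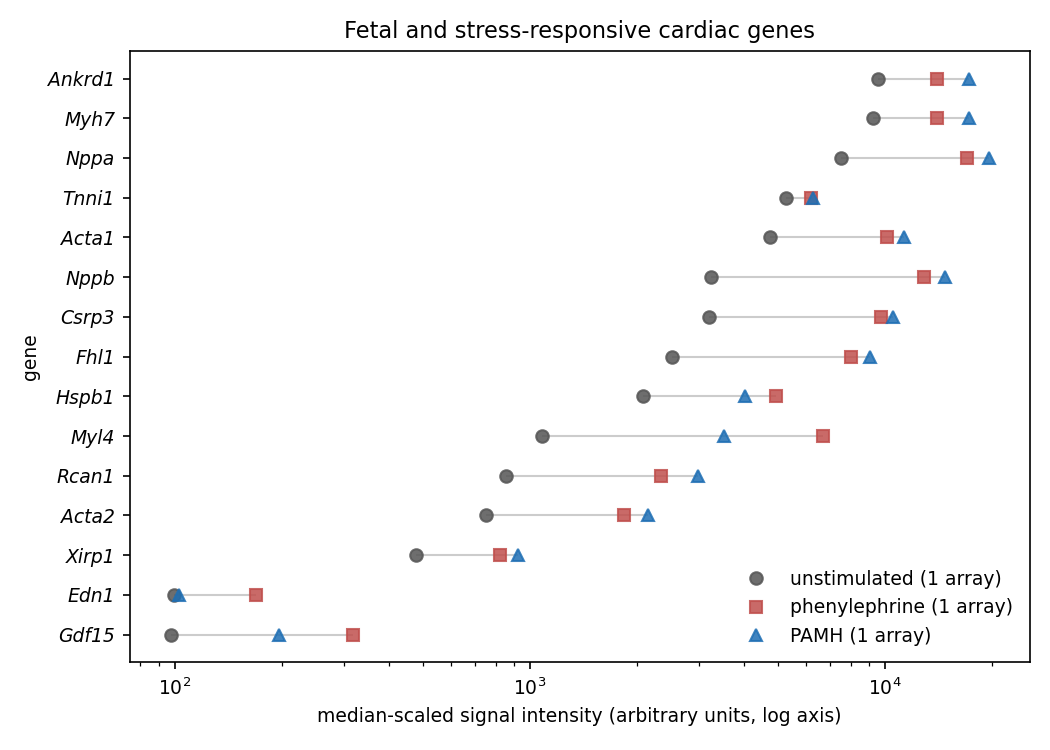
Median-scaled signal intensity (arbitrary units, log axis) of the 15 fetal and stress-responsive cardiac genes on the unstimulated, phenylephrine and PAMH arrays, 1 point per array, joined by a grey line from the lowest to the highest. The points of both compounds lie to the right of the unstimulated point for all 15 genes, by little for Tnni1 (log2 ratios 0.23 and 0.26) and, with PAMH, for Edn1 (0.05), and levels of different genes are not comparable with each other.

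Among 21 genes of cholesterol synthesis and uptake, 10 were at least 1.5-fold higher with phenylephrine and none lower, with a median log2 ratio of 0.56 at percentile 100. The enzymes Fdps (2.68-fold), Idi1 (2.49-fold) and Sqle (2.27-fold) led this list, followed by Hsd17b7 (1.98-fold), whose second probe set had a log2 ratio of 0.17 and whose mean was below 1.5-fold. The unstimulated signal of Hsd17b7 (88.8) was near the floor. Of 21 glycolysis and glucose uptake genes, 7 were higher and 2 lower, with a median of 0.37 at percentile 99.5. The lactate exporter Slc16a3 (5.00-fold), the muscle enolase Eno3 (4.84-fold), the phosphofructokinase Pfkp (log2 ratio 1.58) and the insulin-responsive glucose transporter Slc2a4 (1.71-fold) were higher by their brightest probe sets, but a second one of Slc2a4 had a log2 ratio of 0.05 and the mean of both 0.41, below 1.5-fold, and the aldolase Aldoc was 6.25-fold lower. The glycolysis median fell within the random lists after quantile normalization, at percentile 81.5. Of 20 heat shock protein genes, 7 were higher and none lower, with a median of 0.44 at percentile 99.8, led by the small heat shock protein genes Hspb3 (2.89-fold), Hspb1 (2.37-fold), Hspb8 (1.90-fold) and Hspb6 (1.57-fold), the last with a log2 ratio of 0.39 after quantile normalization, below 1.5-fold.

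Of 32 cytoskeleton and cell adhesion genes, 12 were higher and 1 lower with phenylephrine, with a median log2 ratio of 0.38 at percentile 100. The tubulin genes Tubb6 (2.68-fold) and Tuba4a (2.21-fold), the membrane-cytoskeleton linker Msn (2.57-fold) and the α-actinin Actn1 (2.41-fold) led it. Of 24 growth factor, cytokine-like and binding protein genes, 7 were higher and 1 lower, with a median of 0.31 at percentile 100. They included Tgfb2 (2.80-fold), the activin subunit gene Inhba (2.78-fold) and its antagonist Fstl3 (2.39-fold), besides Gdf15, and without a filter on dim genes this list lay at percentile 48.4. The unstimulated signals of Inhba (78.0), Fstl3 (77.0) and Gdf15 (97.2) were near the floor of 76.0. With an offset of 50, Fstl3 had a log2 ratio of 0.88, below 2-fold. Of 31 cell cycle and DNA replication genes, 7 were higher and none lower, with a median of 0.26 at percentile 99.4 (96.7, within random lists, over genes with 1 probe set), and Ccnd1, Ube2c, Kif20a and Ccnb1 lay between 1.71-fold and 1.77-fold higher. Of 21 genes of Gq and MAP kinase signalling and its feedback, 4 were higher and none lower, with a median of 0.24 at percentile 98.2. These were Map2k3, a kinase upstream of p38 (2.20-fold), Rgs2, which shortens Gq signals (1.91-fold), the phosphatase gene Dusp1 (1.66-fold) and Spry2 (1.59-fold), and the list stood apart under 4 of 11 processing alternatives. After quantile normalization Dusp1 (log2 ratio 0.57) and Spry2 (0.56) were below 1.5-fold, and a second probe set of Dusp1 had 0.45.

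Markers of other cell types went different ways on the phenylephrine array. Of 11 smooth muscle markers, 5 were higher and none lower, with a median log2 ratio of 0.52 at percentile 99.7, but the difference from random lists turned to -0.05 without a filter on dim genes. Cnn1, which encodes calponin (7.20-fold), Synpo2 (2.60-fold), Acta2 (2.44-fold) and Myl9 (1.96-fold) led it. Of 30 extracellular matrix and fibroblast markers, 3 were higher and 2 lower, with a median of -0.04 at percentile 0.92, and this list stood apart under 9 of 11 alternatives. Col6a1 (1.69-fold lower), Dcn, which encodes decorin (1.62-fold lower), Fbn1 (1.45-fold lower) and Lum (1.40-fold lower) were its lowest members, and a second probe set of Fbn1 had a log2 ratio of -0.06. Endothelial, macrophage, erythroid and Schwann cell or neuronal markers each had fewer than 5 measured genes, and of these Cd74 of antigen-presenting cells was furthest from 0, with a log2 ratio of -0.60.

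Lists that lay below random lists held small ratios. The 27 oxidative stress and metal response genes had a median log2 ratio of -0.15 at percentile 0.050, with none higher and 3 lower. The glutathione S-transferase genes Gstm1 (1.71-fold lower) and Gsta1 (1.59-fold lower), the heme oxygenase gene Hmox1 (1.59-fold lower) and Gclm of glutathione synthesis (1.46-fold lower) led it. The 24 genes of ER stress and secretory chaperones had a median of -0.03 at percentile 1.69, with none higher and 1 lower, and stood apart under 8 of 11 alternatives. Trib3 was 1.55-fold lower, Herpud1 1.33-fold, Ddit3 1.33-fold and Creld2 1.30-fold.

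Among genes above the floor on both arrays, the one furthest above its unstimulated level was Casq1, the skeletal isoform of the calcium buffer calsequestrin, at 13.7-fold with phenylephrine. The genes that follow are ranked among those with a mean signal above percentile 60. Besides Cnn1, Myl4, Slc16a3 and Eno3, Inha, which encodes the inhibin α subunit (8.30-fold), Snap91, a clathrin adaptor gene (5.86-fold), Ildr2 (5.16-fold), the creatine kinase Ckb (4.87-fold) and Pdlim7 (4.86-fold) followed, and a second probe set of Pdlim7 had a log2 ratio of only 0.23. Inha had an unstimulated signal of 91.3, near the floor. Myh3, the embryonic myosin heavy chain, was below the floor on the unstimulated array and at least 6.88-fold higher, with Cspg4 at least 5.64-fold, Wfdc1 at least 4.60-fold and the fast skeletal light chain Myl1 at least 4.01-fold. On the lower side, Bcl2l11, which encodes the pro-apoptotic protein Bim, was 6.43-fold lower by 1 of its 3 probe sets, the others not being above the floor on both arrays. The phenylephrine signals of Bcl2l11 (83.5) and Aldoc (88.9) were near the floor. Dhrs7c of the sarcoplasmic reticulum was 6.13-fold lower, Slc4a1ap 3.74-fold, the cardiac gene Lrrc10 3.24-fold, the lipolysis inhibitor G0s2 3.03-fold, S100a13 2.87-fold, Nrep 2.82-fold and Pik3ip1, an inhibitor of phosphoinositide 3-kinase, 2.77-fold. Ntn1, which encodes netrin 1, was below the floor with phenylephrine and at least 4.71-fold lower. Of the receptors, the α1B-adrenergic receptor gene Adra1b was 3.27-fold lower, and the serotonin receptor gene Htr2a was higher by a log2 ratio of 0.62. The unstimulated signal of Htr2a (97.2) was near the floor. Its ratio was below 1.5-fold on the deposited intensities (0.49), with scaling on percentile 75 (0.58) and with an offset of 50 (0.44). Adra1a and Htr2b lay below the floor on all 3 arrays. Gapdh was measured by control probe sets alone, with log2 ratios from 0.27 to 0.37.

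Of 31 genes past 2-fold with phenylephrine and a second measured probe set, 30 had it on the same side, and the split of 172 higher and 50 lower genes depended on the scaling, being 132 and 92 on the deposited intensities and 139 and 71 after quantile normalization. Of 30 lists examined, 10 lay above and 3 below random lists, where 1.5 would for lists of randomly drawn genes. Members of a list may vary together between any cultures, and some lists share members, so these numbers are no test of a treatment.

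**Figure D2:**
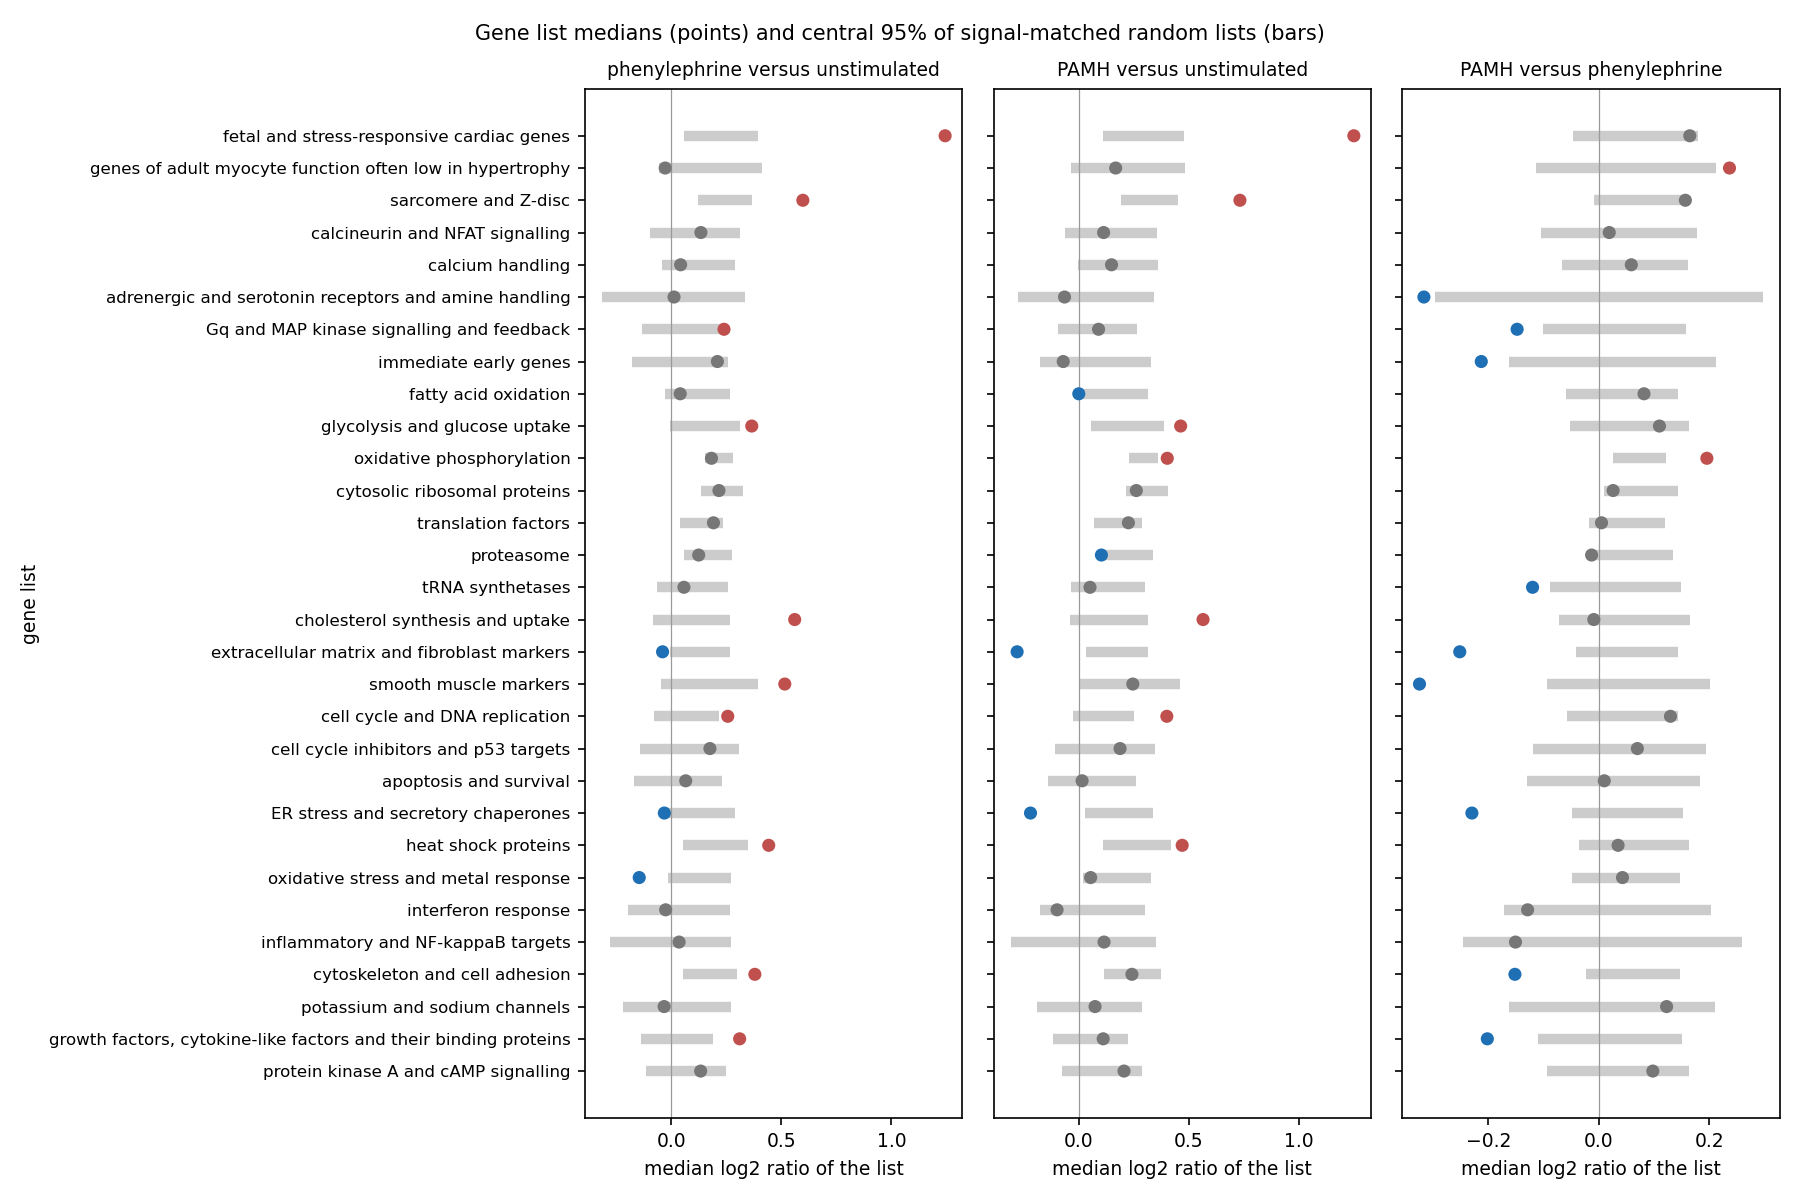
Median log2 ratio of each gene list (points) in the 3 comparisons, with the central 95% of the medians of 10000 signal-matched random lists (grey bars); red points lie above the bar, blue points below it and grey points within it, and the right panel has a narrower axis. Fetal and stress-responsive cardiac genes have the highest medians with both compounds (1.24 and 1.25), and extracellular matrix and fibroblast markers lie below their bar in all 3 panels.

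The second comparison asked the same of PAMH. The fetal and stress-responsive cardiac genes were again higher, with a median of 2.38-fold over 15 genes, 13 of them at least 1.5-fold higher and none lower. Nppb was 4.57-fold higher, Nppa 2.61-fold, Acta1 2.38-fold and Rcan1 3.47-fold. Sarcomere, cholesterol synthesis and cell cycle genes were higher, whereas extracellular matrix and fibroblast genes, led by the matrix protein gene Postn (3.40-fold lower), and genes of ER stress and secretory chaperones were lower than genes of like signal. Of 6548 genes measured on both arrays, 134 were at least 2-fold higher and 52 at least 2-fold lower with PAMH.

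With PAMH the fetal and stress-responsive list had a median log2 ratio of 1.25 at percentile 100, and Fhl1 (3.61-fold) and Csrp3 (3.29-fold) were among its leading members. Of 24 sarcomere and Z-disc genes, 14 were at least 1.5-fold higher and none lower, with a median of 0.73 at percentile 100. Myl4 was 3.26-fold higher, Pdlim3 3.04-fold and Tcap 2.47-fold. Myh7 had a log2 ratio of 0.90 that became 0.33 after quantile normalization, with a second probe set at 1.52. After cyclic loess the log2 ratios of Nppa and Acta1 were 0.86 and 0.79, below 2-fold, and that of Nppb was 1.72. The log2 ratios of Myh6 (0.30) and Atp2a2 (0.17) turned to -0.30 after quantile normalization and -0.29 after cyclic loess, so neither had a settled direction. Further probe sets had -0.08 for Myh6 and -0.25 and -0.41 for Atp2a2. Of 21 cholesterol synthesis and uptake genes, 10 were higher and none lower, with a median of 0.57 at percentile 100. They included Tm7sf2 (2.79-fold), Fdps (2.53-fold), Hsd17b7 (2.24-fold, with a second probe set at a log2 ratio of -0.05 and a mean below 1.5-fold) and Pmvk (2.08-fold). Of 32 cell cycle and DNA replication genes, 12 were higher and none lower, with a median of 0.40 at percentile 100, led by the cyclin Ccnb1 (1.86-fold), the topoisomerase Top2a (1.85-fold), Ube2c (1.84-fold) and the mitotic kinesin Kif20a (1.73-fold). Of 20 heat shock protein genes, 8 were higher and none lower, with a median of 0.47 at percentile 99.3, led by Hspb3 (3.27-fold), Hspb6 (2.22-fold), Hspb1 (1.93-fold) and Hspb7 (1.72-fold), of which Hspb7 had a log2 ratio of 0.47 after quantile normalization and after cyclic loess, below 1.5-fold, and Hspb6 0.82 and 0.86, below 2-fold.

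Of 20 glycolysis and glucose uptake genes, 7 were higher and 3 lower with PAMH, with a median log2 ratio of 0.46 at percentile 99.6. Slc16a3 (3.38-fold), Pfkp (2.63-fold), Slc2a4 (2.05-fold, with a second probe set at a log2 ratio of 0.54) and Pgam1 (1.60-fold, but a log2 ratio of 0.30 after quantile normalization, below 1.5-fold) were higher, and the list lay at percentile 88.7 after cyclic loess. Of 86 oxidative phosphorylation genes, 10 were higher and none lower, with a median of 0.40 at percentile 99.9, and percentile 92.1 after cyclic loess. Ndufa3 (1.75-fold), Cox6a1 (1.75-fold), Ndufb6 (1.75-fold) and Atp5me (1.68-fold) led it, with log2 ratios from 0.43 to 0.49 after quantile normalization. Fatty acid oxidation and proteasome genes lay below random lists in the main setting but not in most others. The 26 fatty acid oxidation genes had a median of -0.00 (mean 0.08) at percentile 1.95, with 3 higher and 1 lower, and stood apart under 5 of 11 alternatives; Hadh (1.95-fold), Eci1 (1.46-fold), Acaa2 (1.45-fold) and Slc27a1 (1.23-fold) were lowest. The 40 proteasome genes had a median of 0.10 at percentile 1.74, with 1 higher and 1 lower, and stood apart under 4 of 11 alternatives. Psmd10 (1.53-fold lower), Psmf1, Psme3ip1 and Psme2 were lowest, of which Psme3ip1 was in the list by its symbol alone.

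Of 30 extracellular matrix and fibroblast markers, 8 were at least 1.5-fold lower and 1 higher on the PAMH array, with a median log2 ratio of -0.28 at percentile 0, and the list stood apart under all 11 alternatives. Postn, the collagen gene Col3a1 (2.09-fold lower), Lum, which encodes lumican (2.06-fold lower), and the fibrillin gene Fbn1 (1.91-fold lower) were lowest, and a second Fbn1 probe set had a log2 ratio of -0.41. Smooth muscle markers, at percentile 52.6, did not go with them. Of the other cell type markers, each with fewer than 5 measured genes, Aif1 of macrophages (log2 ratio 0.56) and Cd74 (-0.52) were furthest from 0. The 24 genes of ER stress and secretory chaperones had a median of -0.22 at percentile 0, with none higher and 2 lower, again under all 11 alternatives. Trib3 was 2.13-fold lower, the cochaperone gene Dnajb9 1.92-fold, and the disulfide isomerase genes Pdia6 and Pdia4 1.43-fold and 1.41-fold.

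Among genes above the floor on both arrays and with a mean signal above percentile 60, those furthest above the unstimulated array with PAMH were Casq1 (8.31-fold), Cnn1 (5.60-fold), Snap91 (5.39-fold) and Ildr2 (5.27-fold), besides Nppb. They were followed by Mllt11 (4.05-fold), the actin regulator Enah (4.01-fold), Akip1 (3.99-fold, with log2 ratios of 2.03 to 2.22 on 3 further probe sets) and Ckb (3.71-fold). Myh3 was at least 11.1-fold higher and LOC102553868 at least 4.10-fold higher. On the lower side, Bcl2l11 was 4.01-fold lower, the anchoring protein gene Sphkap 3.78-fold, the connexin 40 gene Gja5 3.51-fold, Aldoc 3.48-fold, Lrrc10 3.42-fold, Rgma 3.40-fold, the Notch ligand Jag1 3.17-fold, the collagen gene Col14a1 2.97-fold and Coq8a of coenzyme Q synthesis 2.83-fold. Second probe sets of Gja5 and Col14a1 had log2 ratios of -0.44 and -0.49. Dhrs7c was at least 9.37-fold lower. Adra1b was 2.38-fold lower, Htr2a had a log2 ratio of 0.30, and the Gapdh control probe sets lay between 0.46 and 0.56.

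Whether more genes were higher or lower with PAMH depended on the scaling: 75 were higher and 92 lower on the deposited intensities, 86 and 74 after quantile normalization, 85 and 70 after cyclic loess, and 42 and 226 when hybridization spike controls were made equal, an alternative added after seeing the data. Of 30 lists examined, 7 lay above and 4 below random lists, where 1.5 would for lists of randomly drawn genes, which again is no test of a treatment. Of 29 genes past 2-fold with a second measured probe set, 24 had it on the same side.

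The third question was how far both compounds went with the same genes. Of 6399 genes measured on all 3 arrays, 91 were at least 2-fold higher with both compounds and 20 at least 2-fold lower with both, and none was 2-fold higher with one and 2-fold lower with the other. Independent lists of these lengths would share 3.60 higher and 0.367 lower genes. These lists are not independent, since both comparisons use the same unstimulated array, so the excess over these numbers does not show a common response. Of genes with a mean signal above percentile 60, Casq1, Cnn1, Snap91, Ildr2 and Ckb were among the 10 highest with either compound. Bcl2l11, Aldoc and Lrrc10 were among the 10 lowest with either. At the level of lists, 6 stood above random lists with both compounds (fetal and stress-responsive genes, sarcomere, glycolysis, cholesterol synthesis, cell cycle and heat shock proteins), and 2 below (extracellular matrix and ER stress). The shared unstimulated array can by itself give lists the same direction with both, and these numbers of lists were not set beside simulated arrays. Among the 292 genes past 2-fold with at least 1 compound, 98.3% had the same sign with both. Simulated unchanged arrays gave 93.5% on average and up to 98.6%. With deviations taken from the pair of treated arrays they gave 97.2% on average and up to 100%. The shared array alone can therefore give such a share, and no common response is read from it. Of the 292 genes, the ratio with phenylephrine was the larger in size for 179.

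Across genes, which are not independent replicates, the log2 ratios of both compounds correlated with a Pearson r of 0.770 and a Spearman rho of 0.722. Both sets of ratios share 1 unstimulated array, and simulated unchanged arrays gave r = 0.50, with 4.40 genes on average (at most 13) higher with both and 4.40 (at most 11) lower with both. The simulated lists were shorter, with 37.1 higher genes per comparison on average against 172 and 134, so the shared counts cannot be compared directly. The covariance was 0.137 against 0.0761 in the simulation, a difference of 0.0612. With deviations taken from the pair of treated arrays alone, an alternative added after seeing the data, the simulated covariance was 0.0411. With 1 unstimulated array no split of the control was possible, and some or all of the excess may come from that array. The counts moved with the scaling, to 59 higher and 36 lower with both on the deposited intensities, 62 and 29 after quantile normalization, 60 and 26 after cyclic loess, and 40 and 44 on the spike controls.

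**Figure D3:**
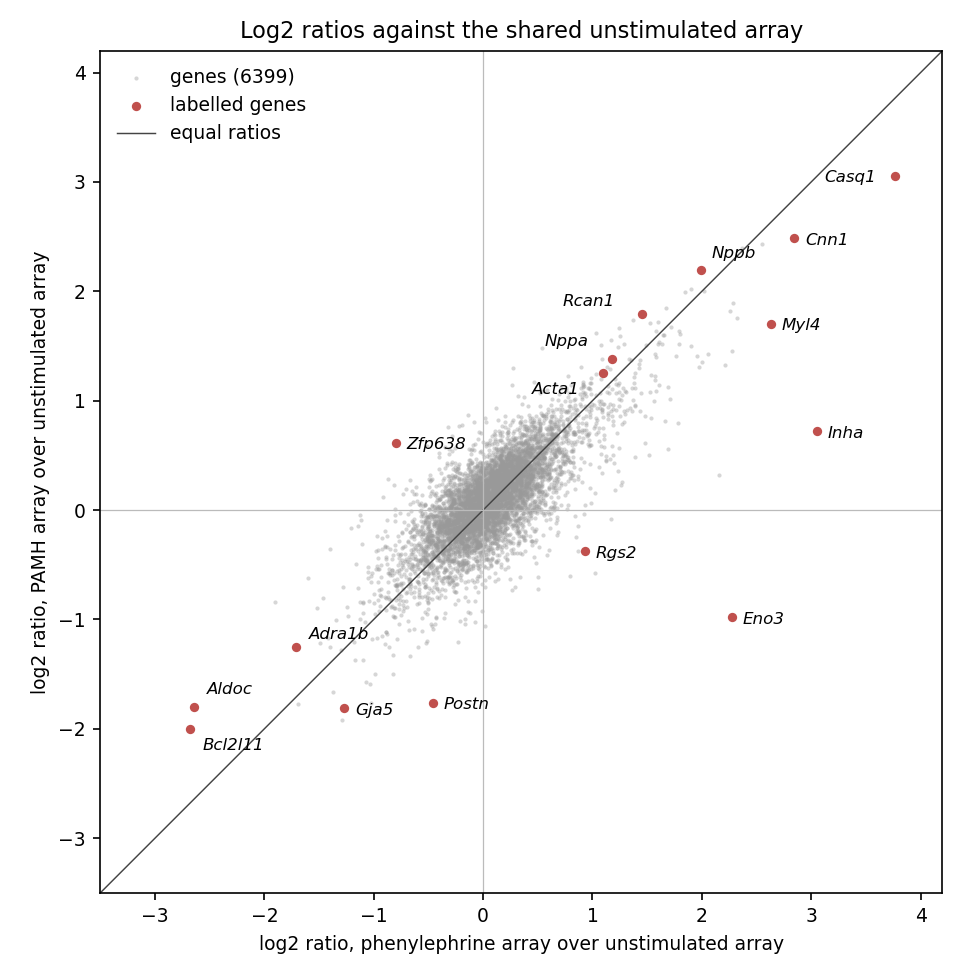
Log2 ratio against the unstimulated array with phenylephrine (horizontal axis) and with PAMH (vertical axis), 1 grey point for each of 6399 genes, with labelled genes in red and a diagonal line of equal ratios. Most genes far from 0 lie near the diagonal, while Eno3 (2.28 and -0.98), Inha, Rgs2, Postn and Zfp638 lie far from it.

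The direct comparison asked where PAMH differed from phenylephrine, at the differing doses used. Relative to the median-scaled arrays, genes of oxidative phosphorylation were slightly higher with PAMH, with a median of 1.15-fold over 86 genes. This is a log2 ratio of 0.20, against 0.07 for the median random list. Scaling on the spike controls put the median of all non-control probe sets at -0.37, a larger shift, so the position among other genes is shown but the direction depends on the scaling. Extracellular matrix and fibroblast genes, smooth muscle markers and genes of ER stress and secretory chaperones were lower, with medians of 1.19-fold, 1.25-fold and 1.17-fold. Among genes above the floor on both arrays and with a mean signal above percentile 60, Eno3, the muscle enolase, differed most. It was 9.56-fold lower with PAMH, followed by Inha at 5.04-fold lower. Of 6592 genes measured on both arrays, 13 were at least 2-fold higher and 24 at least 2-fold lower with PAMH than with phenylephrine.

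For the fetal and stress-responsive list the median log2 ratio of PAMH over phenylephrine was 0.17, within the random lists at percentile 95.1. None of its 15 genes was higher at 1.5-fold and 3 were lower, Myl4 (-0.93), Edn1 (-0.72) and Gdf15 (-0.69). Rcan1 had a ratio of 0.34. After quantile normalization the ratios of Nppa (0.21) and Myh7 (0.30) were 0.00 and 0.06, and those of Nppb (0.20) and Acta1 (0.16) turned to -0.08 and -0.02. The 86 oxidative phosphorylation genes had a median of 0.20 at percentile 100 under the main processing, with 1 higher and none lower, and stood apart under all 11 alternatives. Ndufa3 (1.53-fold), Ndufa5 (1.42-fold), Cox8b (1.36-fold) and the assembly factor gene Ndufaf8 (1.36-fold) led it. The log2 ratio of Ndufa3 was below 1.5-fold on the deposited intensities (0.584), after quantile normalization (0.554) and after cyclic loess (0.545). The 9 measured genes of adult myocyte function had a median of 0.24 at percentile 99.1, with none past 1.5-fold, and percentile 90.5 after quantile normalization. Ppargc1a, a regulator of mitochondrial biogenesis (1.44-fold), Myh6 (1.25-fold), Slc2a4 (1.20-fold) and Casq2 (1.19-fold) led it. The phenylephrine signal of Ppargc1a (77.1) was near the floor of 76.0.

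Of 30 extracellular matrix and fibroblast markers, none was higher and 5 were lower with PAMH than with phenylephrine, with a median log2 ratio of -0.25 at percentile 0. Postn (2.47-fold lower), the crosslinking enzyme Lox (2.01-fold), Timp1 (1.68-fold) and Col12a1 (1.59-fold) were lowest. With PAMH, Lox (signal 234 against 196) and Timp1 (507 against 401) still lay above the unstimulated array, while Postn and Col12a1 lay below it. Of 11 smooth muscle markers, none was higher and 2 lower, with a median of -0.32 at percentile 0.0050. Myh11 (1.58-fold lower), Actg2 (1.52-fold), Tagln (1.42-fold) and Cnn1 (1.29-fold) were lowest. Of 24 genes of ER stress and secretory chaperones, none was higher and 3 were lower, with a median of -0.23 at percentile 0, led by Sel1l (1.57-fold lower), Dnajc3 (1.53-fold), Dnajb9 (1.51-fold) and Trib3 (1.37-fold). Of 31 cytoskeleton and adhesion genes, none was higher and 4 were lower, with a median of -0.15, led by Nes (1.67-fold lower), Tubb2a (1.61-fold), Anxa1 (1.60-fold) and Itga1 (1.53-fold). These 4 lists stood apart under all 11 alternatives. With an offset of 50, however, Col12a1, Myh11, Actg2, Sel1l, Dnajc3, Dnajb9 and Itga1 fell below 1.5-fold and Lox below 2-fold. The 7 measured macrophage and leukocyte markers lay at percentile 86.9, and the 31 cell cycle and DNA replication genes at 95.4, above random lists under 4 of 11 alternatives.

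Of 25 growth factor, cytokine-like and binding protein genes, none was higher and 6 were lower with PAMH than with phenylephrine, with a median log2 ratio of -0.20, and 9 of 11 alternatives kept the list apart. Hbegf (1.84-fold lower), Inhba (1.81-fold), the endothelin gene Edn1 (1.65-fold) and Gdf15 (1.61-fold) were lowest. None of these was below its unstimulated signal with PAMH, with 182 against 142, 119.5 against 78.0, 103 against 99.2 and 197 against 97.2. The 20 genes of Gq and MAP kinase signalling had a median of -0.15 at percentile 0.48, with 1 higher and 3 lower, but a difference from random lists of 0.03 over genes with 1 probe set. Rgs2 was 2.48-fold lower, with a second probe set at a log2 ratio of -1.47, Spry2 1.87-fold, Plcb3 1.51-fold and Dusp5 1.47-fold. The 11 immediate early genes had a median of -0.21 at percentile 0.70, with none higher and 1 lower, and lay within random lists with a floor at percentile 60 (percentile 9.37) and over genes with 1 probe set (3.13). Klf6 (1.62-fold lower), Nr4a1 (1.46-fold), Atf3 (1.36-fold) and Nr4a3 (1.34-fold) were lowest, but a second probe set of Klf6 had a log2 ratio of -0.16 and the mean of both -0.43, within 1.5-fold. The 21 tRNA synthetase genes had a median of -0.12 at percentile 0.78 with none past 1.5-fold, led by Tars1 (1.34-fold lower), Fars2, Wars1 and Kars1, and stood apart under 7 of 11 alternatives. The 5 measured genes of adrenergic and serotonin receptors and amine handling had a median of -0.32 at percentile 1.92 with none past 1.5-fold. Maoa, which encodes a monoamine oxidase, was 1.38-fold lower, Htr3a 1.35-fold (PAMH signal 76.6, near the floor of 76.0) and Htr5a 1.06-fold. That median was the ratio of Htr2a, whose second probe set had 0.41, and the mean of all probe sets put the list at percentile 23.4. Adra1b had a ratio of 0.45.

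Besides Eno3, Inha, Rgs2 and Postn, the lowest genes above the floor on both arrays and with a mean signal above percentile 60 were Wfdc1 (3.92-fold lower), the prostacyclin synthase gene Ptgis (3.57-fold), Fibin (3.03-fold), Tnfrsf11b, which encodes osteoprotegerin (2.93-fold), Nudt18 (2.38-fold) and Ripk3 of necroptosis (2.35-fold). Except for Postn, these genes were higher with phenylephrine than on the unstimulated array. With PAMH, Inha (signal 150 against 91.3) and Ptgis (206.5 against 165) also lay above it, Wfdc1 was below the floor on it, and the rest lay below it. Myl1 was at least 4.01-fold lower. The highest genes with a mean signal above percentile 60 were Zfp638 (2.66-fold), Hopx, a homeodomain-only protein gene of heart (2.14-fold), the GTPase gene Rrad (2.12-fold), the T-type calcium channel gene Cacna1g (2.11-fold), Slc4a1ap (2.09-fold), the sorting receptor gene Sorl1 (2.06-fold), Scrn3 (2.04-fold), Mras (2.04-fold), Crip1 (1.99-fold) and G0s2 (1.98-fold). The 13 genes at least 2-fold higher include dimmer ones not named here. The levels of Cacna1g, Slc4a1ap, Sorl1 and G0s2 with PAMH were at or below the unstimulated ones, with signals of 245 against 252, 273 against 488, 242 against 272 and 1242 against 1905. Of 31 lists examined, 2 lay above and 9 below random lists, where 1.55 would for lists of randomly drawn genes, again no test of a treatment. On the spike controls 1 gene was 2-fold higher and 114 were lower. Of the 6 genes past 2-fold with a second measured probe set, 4 had it on the same side.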

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

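The test that set the variance of the unstimulated array against that of the other arrays was chosen after the result was seen, the core fibroblast genes were chosen after the values of Postn and Lox among them had been seen, and Serpinf1 and the hexokinase probe sets were picked after their values were seen.

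Of the genes that went opposite ways with the compounds, Eno3, a muscle enolase, had a log2 ratio against the unstimulated array of 2.28 with phenylephrine and -0.98 with PAMH, and the zinc finger gene Zfp638 had -0.80 and 0.62. Serpinf1, with 0.79 and -0.60, was the remaining gene of 3 that passed 1.5-fold in opposite directions. These differences were not tested, since each rests on 1 array per condition.

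Signal was also present in probe sets outside the gene comparisons. Of 1349 measured probe sets without a single gene name, 18 were at least 2-fold higher and 12 lower with phenylephrine than on the unstimulated array, and of 1360 with PAMH, 13 were higher and 8 lower. The control probe set for the middle of hexokinase had log2 ratios of 1.05 with phenylephrine and 1.77 with PAMH, while those for its 3′ part had 0.46 and 0.90.

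The ratios of both compounds against the unstimulated array correlated across genes (r = 0.770), and the design offers a biological explanation, a response common to both compounds, and technical ones. Noise of equal size on the 3 arrays is argued against: the variance that belongs to the unstimulated array alone was 2.76 times the larger of the variances of the other arrays, with a 95% bootstrap interval over genes of 2.47 to 3.11, which restates r = 0.770 against the 0.50 of equal noise, since that variance is the covariance of both sets of ratios, and is no separate evidence. A trend of the ratio with signal is also argued against as the whole cause, since r was 0.757 after cyclic loess, against 0.50 from a shared array alone. What stays open is an unstimulated culture or array that stands apart from others of its kind, since 0 other unstimulated arrays were there to compare. A common response and an unusual unstimulated array cannot be told apart here.

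Extracellular matrix and fibroblast markers were lower on the PAMH array, among them Col3a1, Col1a2 and Col1a1, the core fibroblast genes with the brightest probe sets, with signals of 2773, 2299 and 1977 on the unstimulated array and 1327, 1900 and 1264 on the PAMH array. On the phenylephrine array they were 2011, 1914 and 1621, so all of them were lower than unstimulated with both compounds, and Col1a2 by a like amount. A trend of the ratio with signal is argued against, since the list lay at percentile 0 of signal-matched random lists, in the main setting and after cyclic loess. The matching already allows for such a trend, so the result after cyclic loess adds little. The trend also ran the other way, with a median log2 ratio of 0.31 in the brightest class of genes with PAMH. Fewer fibroblasts in the PAMH culture may account for it, and would lower fibroblast genes by a like amount: 12 of the 14 measured core fibroblast genes lay below signal-matched genes, but with log2 ratios from -1.76 (Postn) to 0.26 (Lox), and all 14 also belong to the list whose difference they are to explain. Their SD was 1.89 times the spread between probe sets of 1 gene, with a 95% bootstrap interval of 1.04 to 2.51 around the limit of 1.5 set for it, so fewer fibroblasts and a lower expression of matrix genes cannot be told apart. An effect of PAMH on these genes stays open and was not tested in further cultures. An unstimulated culture or array that stands apart may also add to the difference from it. It has no part in the lower median of the list with PAMH than with phenylephrine (log2 ratio -0.25).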

How the results depend on the processing

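Scaling on the hybridization spike controls, and simulated noise from the pair of treated arrays, were chosen after seeing the data. No paired analysis was possible because each group had 1 array.

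The correlation of both compounds' ratios lay between 0.709 and 0.808 under all 10 alternatives run. Of the alternative values of single genes, 1718 moved by less than the SD between probe sets and 110 by more, and none of those at 2-fold or more changed sign. Of 104 named ratios at 2-fold, 23 were below it under at least 1 alternative, and of 57 others at 1.5-fold, 31 were below that, by setting 15 and 16 with an offset of 50, 10 and 12 after cyclic loess, 9 and 12 after quantile normalization, 5 and 6 on the deposited intensities, 2 and 3 with the mean of probe sets, and 2 and 2 on percentile 75. Scaling on the spike controls was not among the settings for these named ratios, so more of them may be lost there. Over all genes it kept 40 of the 134 calls higher with PAMH than unstimulated, and 1 of the 13 higher with PAMH than with phenylephrine. For gene lists, 904 alternatives left the call as it was, 47 ended it, 33 added one and 3 turned the difference from random lists: smooth muscle markers with phenylephrine without a filter (-0.0526), Gq and MAP kinase signalling between the compounds over genes with 1 probe set (0.0327), and the proteasome with PAMH against unmatched random lists (0.0048). A count of genes stayed within 1.5 times its main value in 57 cases and left that range in 47, given below by setting, and the number of lists apart stayed in it in 32 cases and left it in 1.

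On the deposited intensities, 92 genes were lower with phenylephrine, 75 higher and 92 lower with PAMH, and 59 higher and 36 lower with both; the median shift of -0.13 and -0.15 that this setting keeps accounts for the direction. Of the 75 and 92 with PAMH, 74 and 50 were also counted in the main setting. Quantile normalization left 86 higher with PAMH, and cyclic loess 85 with PAMH and 60 with both. On the spike controls, which put the median of all non-control probe sets at -0.42 between PAMH and unstimulated, 42 were higher and 226 lower with PAMH, 1 higher and 114 lower between PAMH and phenylephrine, and 40 higher and 44 lower with both.

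A floor at percentile 20 admits dimmer genes and gave 259 higher and 100 lower with phenylephrine, 204 and 129 with PAMH, 54 and 97 between the compounds, and 37 lower with both. A floor at percentile 60 left 21 lower with phenylephrine, 26 lower with PAMH, 3 higher and 11 lower between the compounds, and 11 lower with both. An offset of 50, which shrinks the ratios of dim genes, left 23 lower with phenylephrine, 30 lower with PAMH, 2 higher and 10 lower between the compounds, and 12 lower with both. Over genes with 1 probe set, 7 lists stood apart between the compounds, against 11 in the main setting; the cause was not tested.

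At 1.5-fold, 585 genes were higher and 297 lower with phenylephrine, 610 and 273 with PAMH, 127 and 176 between the compounds, and 371 and 137 with both. At 3-fold these were 41 and 7, 26 and 9, 0 and 5, and 19 and 3. Signal over background limits the comparison to genes above the floor, and a gene that drops below it is not counted as lower: of 25 genes simulated at 4-fold lower with phenylephrine, 14 stayed measured.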

Other observations

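The gene sets for skeletal muscle and for BMP and SMAD targets, and all genes named here outside the lists' leading members, were chosen after the ratios had been seen, although each test's outcome was not known when its expectation was written.

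Several lists that lay within random lists in the main setting held genes far from their unstimulated level. Among genes of cell cycle inhibition and the p53 response, with list medians at percentile 80.1 for phenylephrine and 69.5 for PAMH, but above random lists with a floor at percentile 60 (99.68 and 99.95) and over genes with 1 probe set (99.79 and 99.97), the growth arrest gene Gadd45g had log2 ratios of 1.80 and 1.61, the imprinted inhibitor Cdkn1c -0.82 and -1.50, and the p53 target Perp -0.99 and -0.85. In the calcium handling list, at percentiles 14.8 and 32.7, the T-type channel gene Cacna1g stood at -1.12 with phenylephrine and -0.04 with PAMH, and the exchanger gene Slc8a1 at 0.39 and 0.77. In the list of potassium and sodium channels, at percentiles 33.2 and 56.9, the sodium pump subunit gene Atp1b1 had 1.35 and 1.37, and the sulfonylurea receptor gene Abcc9 -0.67 and 0.05. The phosphodiesterase gene Pde4b of the cyclic AMP list, which lay above random lists with PAMH under 2 of 11 alternatives, had 0.50 with phenylephrine and -0.72 with PAMH.

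In the main setting, lists for protein synthesis did not stand apart from genes of like signal with either compound. The 42 cytosolic ribosomal protein genes lay at percentile 42.7 with phenylephrine and 16.0 with PAMH, but with PAMH below random lists after quantile normalization (1.25) and cyclic loess (0.36), and translation factors at 85.4 and 75.7. Against unmatched random lists both lay above with either compound. Calcineurin and NFAT signalling genes lay at 59.4 and 35.2, although Rcan1 of this list was 2.73-fold and 3.47-fold higher. Interferon response genes lay at 27.9 and 10.4 (2.23 with PAMH and a floor at percentile 60), and apoptosis and survival genes, which include Bcl2l11, at 63.0 and 33.0.

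Casq1, Myh3, Tcap and Mybpc2, all known from skeletal muscle, were among the genes furthest above the unstimulated array, with Mybpc2 at a log2 ratio of 1.90 with phenylephrine. The hypothesis that skeletal muscle genes were higher more widely was tested on 37 other such genes, of which 10 were measured in each comparison. Their median lay at percentile 34.4 of signal-matched random lists with phenylephrine and 25.8 with PAMH, but this decides nothing about a wider increase. The expectation written for it was wrong in its design, since the set left out genes already seen higher, among them Eno3 and Myl1 with phenylephrine, and the floor drops genes that start below it, with 10 of 32 on the array measured. Of those measured, Myh1, the adult fast myosin heavy chain, was the furthest above with 1.25 and 1.59.

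Id1, Id2 and Id3, targets of BMP signalling that hold back differentiation, had log2 ratios of -1.13, -0.98 and -1.10 between PAMH and phenylephrine. The hypothesis that other BMP and SMAD targets were lower with PAMH as well was tested on 17 genes, of which 6 were measured. Their median lay at percentile 28.2, with none past 1.5-fold in either direction. Since the set left out the Id genes and 6 of its 13 genes on the array were measured, the expectation written for it was likewise wrong in its design, and a wider difference stays open.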
